A study of Mus musculus with 18 samples.

How the data were processed

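RNA of the mouse cochlear nucleus, the first brainstem station of the auditory pathway, was measured on 2 kinds of array at postnatal day 7 (P7), day 14 (P14) and day 21 (P21). Per the labels, the tissue came from C57BL/6J mice, and each oligonucleotide array was hybridised with RNA pooled from 5 pups. There were 3 oligonucleotide arrays at P7, 2 at P14 and 3 at P21. One P21 label counts fewer replicates than the other labels and the series' design text do, and all 3 P21 arrays were used. The spotted cDNA array compared P7 with P21 in 5 hybridisations of 2 channels each. Per the labels, P21 was in Cy5 and P7 in Cy3 in 4 of them, and the dyes were exchanged in hybridisation 5. Hybridisations 1, 2 and 5 used unamplified RNA pooled from 20 pups, and hybridisations 3 and 4 used RNA from 5 pups that had gone through 1 round of linear amplification. Each replicate is a pool, so the spread between replicates averages over pups. The labels do not state that every pool came from other animals, and p-values then measure only the spread between these samples.

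The deposited table of the oligonucleotide arrays holds scaled intensity values, 1 per probe set, and the submitters' processing notes name GCOS, the array maker's software, with no version. The 2%-trimmed mean was 250.1 on each of the 8 arrays of the deposited table, so the intensity values had been brought to a common level before deposit. The deposited cDNA table holds 1 intensity per spot and channel. How its background was treated is not given in the sources used here. Of the channel values, 131 (0.0859%) were below 0. The trimmed mean of a channel ran from 332 to 1758, so the channels had not been brought to a common level. A channel held between 5 and 25 values below 0, and at most 4 values at or above 65000, near the ceiling of a scanner. For arrays there is no read depth, and the number of arrays limits the precision.

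The tables used here do not pair probes with genes, apart from control probe sets whose identifiers carry a transcript's name, and the gene table at hand names genes by other identifiers. Of the 22690 probe set identifiers 0 matched it, and of the 15247 spot identifiers 0 matched it. For that reason 34 gene lists that had been fixed before the data were examined, and the comparison of genes between the 2 kinds of array, were not run, and probe sets are described by their rank and signal, with no gene named. The rule for named features had been written for genes. It was applied to probe sets and shortened to the 2 largest rises and the 2 largest falls of each comparison, among those past the threshold with non-overlapping arrays of the ages compared. Non-overlap was not asked for the difference between intervals. On the cDNA array, where no spot passed, the rule takes the smallest p-values among spots with one sign in all 5 hybridisations.

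Oligonucleotide values were scaled to a common 2%-trimmed mean of 250.1, which changed them little. The 64 control probe sets were left out, and probe sets with a mean signal under 50.0 (0.2 of the trimmed mean) were not tested, which left 15296 of 22690. The fit used log2(signal + 12.5), where the pseudocount is 0.05 of the trimmed mean. Fold changes are on this scale and understate the changes of dim probe sets, and ranks by size are those at this pseudocount. One limma model (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a trend) held all 8 arrays, so that the ages shared an estimate of the spread. Its contrasts were P21 against P7, P14 against P7, P21 against P14, and the first interval's change minus the second interval's change. All tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The share of the change reached by P14 was the log2 change from P7 to P14 divided by that from P7 to P21, as a median over the probe sets called between P7 and P21. Its error is a jackknife SD over the 8 arrays.

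For the cDNA array, values below 0 were set to 0, channels were scaled to a common trimmed mean of 871, and log2(intensity + 43.5) was taken. The log2 ratio of Cy5 over Cy3 was normalised by loess within each hybridisation and then turned to P21 over P7 as labelled. Spots with a mean under 174 were not tested, which left 12397 of 15247. The ratios of the 5 hybridisations were tested against 0 with limma, with the shared hybridisation as the block.

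Each procedure was tested on simulated data with 200 changed features. Of changes of 1 on the log2 scale, 77% were recovered for P21 against P7, 69% for P14 against P7, 71% for P21 against P14 and 13% for the difference between intervals, among 15296 probe sets. Of changes of 2, 99%, 97%, 99% and 66% were recovered in the same order. In the data, 38.6% of probe sets passed for P21 against P7 and 29.6% for P14 against P7. That is far more than the 200 changed here. The Benjamini-Hochberg cut-off depends on the share changed, so these percentages do not give the sensitivity of each comparison in the data. On the cDNA array, with 12397 spots, 95% of changes of 1 and 100% of changes of 2 were recovered without a dye bias. With the fitted dye term of each spot added, 0% of either size was recovered. When all called probe sets were simulated to have reached 0.5 of their change by P14, the median share came out at 0.498. The P7 arrays enter both changes of the share, and noise shared in this way pulls it towards 0.5. A true share of 0.5 cannot show such a bias, and no other true share was simulated.

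The alternatives fixed beforehand were quantile normalization, the values as deposited, other pseudocounts and filters, no trend, the replicate number as a block, only the arrays of P7 and P21, each array or hybridisation left out in turn and, for the cDNA array, no loess, a dye coefficient, amplified or unamplified RNA alone, an amplification covariate and unpaired channels. Added after seeing the data were a block for the poly-A control found on each array, leaving out the P7 and P21 arrays numbered 1 together, turning the channels of hybridisation 5, keeping the control probe sets of mouse transcripts in the fit, and all settings run for the share reached by P14.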

Results

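The series followed gene expression in the mouse cochlear nucleus, which receives the auditory nerve, over the postnatal weeks around the onset of hearing. Oligonucleotide arrays of 22690 probe sets covered P7 (n = 3), P14 (n = 2) and P21 (n = 3). Median signal per array lay between 98.7 and 110.5. Within an age, log2 signals of any 2 arrays correlated across probe sets at r = 0.966 to 0.983 (probe sets are not independent replicates). The median SD of log2 signal between replicates was 0.15 at P7, 0.10 at P14 and 0.17 at P21. A median SD from 2 arrays tends to come out lower than one from 3, so the P14 value does not show tighter replicates. Spotted cDNA arrays of 15247 spots compared P7 and P21 directly in 5 hybridisations, with median channel intensities of 170 to 1093.

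The first principal component of the 8 oligonucleotide arrays held 61.4% of the variance and ordered the ages, with the P7 arrays between -47.8 and -41.5, the P14 arrays at 17.7 and 17.8 and the P21 arrays between 28.1 and 37.5. The second component, with 13.3%, set the P14 arrays (-23.9 and -22.4) apart from the P21 arrays (6.07 to 16.5), while the P7 arrays spread from -7.34 to 19.7.

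**Figure D1:**
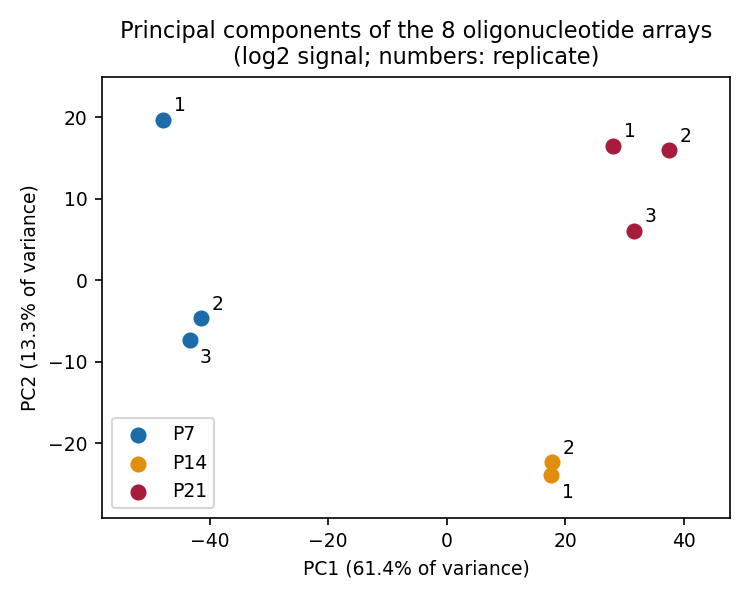
First against second principal component of log2 signal of the 8 oligonucleotide arrays, 1 point per array, coloured by age and numbered by replicate. The P7 arrays lie far to the left of the P14 and P21 arrays on the first component, which holds 61.4% of the variance.

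Each oligonucleotide array also carried a high signal of 1 bacterial poly-A control and little of the others. It was dap on P7 replicates 1 and 2 and P14 replicate 1, lys on P7 replicate 3, P14 replicate 2 and P21 replicate 1, phe on P21 replicate 2 and trpn on P21 replicate 3. Of these, phe and trpn were found only at P21.

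**Figure D2:**
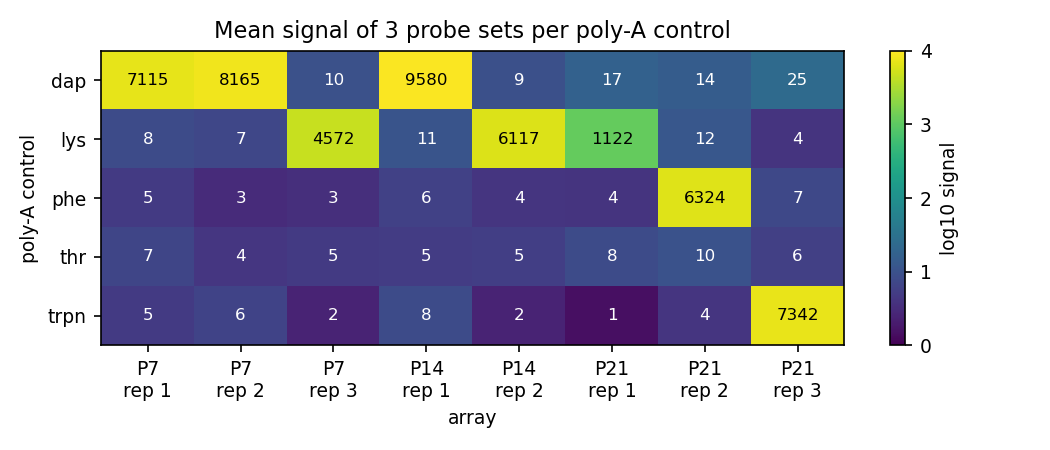
Mean signal of each of 5 poly-A controls (vertical) on each of the 8 oligonucleotide arrays (horizontal), coloured by log10 signal. Each array has 1 control at 1122 to 9580, and the highest of the others is 24.6.

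The comparison of P21 with P7 asked how expression differed between the ends of the period. The probe set with the largest rise went from a signal of 23.3 ± 11.04 (SD, n = 3) at P7 to 581 ± 95.5 (SD, n = 3) at P21, a log2 change of 4.08 (SE 0.22, limma adjusted p = 1.18e-06). The next rose from 36.1 ± 11.1 to 762 ± 117 (SD, n = 3 each), a log2 change of 4.01 (SE 0.19). Both had risen by P14, to 249 ± 26.4 and 318 ± 53.7 (SD, n = 2), with log2 changes from P7 of 2.91 and 2.78. The largest fall was from 452 ± 385 to 4.40 ± 1.85, a log2 change of -4.48 (SE 0.62, limma adjusted p = 0.000316). The arrays of that probe set differed widely before P21, with signals of 249, 211 and 896 at P7 and 556 and 85.5 at P14. The next fell from 1767 ± 549 through 272 ± 4.81 at P14 to 81.2 ± 24.9, a log2 change of -4.23 (SE 0.24, limma adjusted p = 1.59e-06). Probe sets of poly-A controls other than the one found on an array had signals of up to 26.6, so the means of 23.3 and 4.40 lay within that range, and the size and rank of these changes depend on the pseudocount. With a smaller and a larger pseudocount the first rise was 4.58 and 3.11 and the first fall -5.76 and -2.95, and with the larger one the next rise (3.23) and the next fall (-3.76) were the larger.

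Of the 15296 probe sets tested, 5907 (38.6%) differed between P7 and P21 in limma, 2622 higher and 3285 lower at P21. The median absolute log2 change of these was 0.68, and 1378 changed by at least 1 on the log2 scale, 639 upward and 739 downward. In 7569 probe sets (49.5%) all arrays of one age lay above all arrays of the other, where chance gives 10%. When probe sets were divided by brightness into 3 groups of nearly equal size, 24.7% of the dimmest, 38.7% of the middle and 52.5% of the brightest group were called, with a median SE of the log2 change of 0.19, 0.14 and 0.11. With the poly-A control of each array as a block, P21 replicates 2 and 3 each have a control of their own and drop out, so that P21 rests on replicate 1 alone, with 2 residual degrees of freedom, and a lost call there does not show a weaker effect. In that setting 1938 passed, and the probe set with the largest fall had a log2 change of -4.42 and an adjusted p of 0.0649, where its adjusted p over all alternatives ran from 0.000109 to 0.0649.

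**Figure D3:**
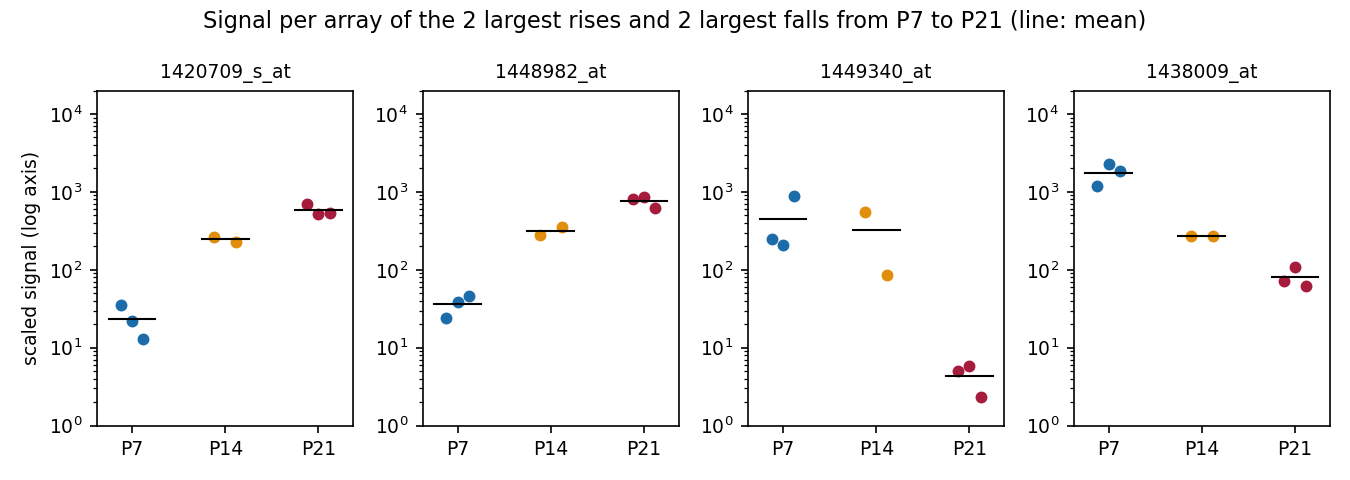
Scaled signal on a log axis, 1 point per array, at P7, P14 and P21, for the 2 probe sets with the largest rise and the 2 with the largest fall from P7 to P21, with the mean of each age as a line and the identifier above each panel. The largest rise goes from a mean of 23.3 to 581, and the largest fall from 452 to 4.40.

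The comparison of P14 with P7 covered the first interval. The probe set with the largest rise went from 2.93 ± 0.25 (SD, n = 3) to 165 ± 3.96 (SD, n = 2), a log2 change of 3.52 (SE 0.17, limma adjusted p = 9.16e-06), and stood at 183 ± 11.6 at P21. The next rose from 443 ± 212 to 4098 ± 156, a log2 change of 3.31 (SE 0.36). The largest fall was from 1191 ± 89.8 to 141 ± 61.9, a log2 change of -3.02 (SE 0.26, limma adjusted p = 5.19e-05), and the next fell from 966 ± 57.9 to 125 ± 51.5, a log2 change of -2.88 (SE 0.38). The first rise started from a mean of 2.93, within the range of controls not found on an array, and was 4.95 with a smaller and 2.02 with a larger pseudocount, where the next rise was 3.19. In all, 4524 probe sets passed, 1967 higher and 2557 lower at P14 (2059 and 2066 after quantile normalization), and 1017 of them changed by at least 1 on the log2 scale. Without one or the other P14 array the count was 2434 or 2378, where the remaining array is assumed to vary like those of the other ages.

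The comparison of P21 with P14 covered the second interval. The probe set with the largest fall went from 9859 ± 3842 (SD, n = 2) to 741 ± 839 (SD, n = 3), a log2 change of -4.29 (SE 0.72, limma adjusted p = 0.0243). Its P21 arrays differed widely, at 1704, 346 and 173. The next was the probe set that also fell most from P7 to P21, with a log2 change of -3.81 (SE 0.70, limma adjusted p = 0.029). The largest rise was from 11.8 ± 2.76 to 102.4 ± 22.7, a log2 change of 2.22 (SE 0.23, limma adjusted p = 0.00467), and the next from 12.5 ± 4.38 to 76.5 ± 19.7, a log2 change of 1.82 (SE 0.24, limma adjusted p = 0.0147). Both had fallen from P7 to P14, with log2 changes of -1.89 and -1.92. Their P14 means of 11.8 and 12.5 lay within the range of controls not found on an array, and with a smaller and a larger pseudocount the rises were 2.86 and 1.29, and 2.40 and 1.01.

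In all, 313 probe sets passed between P14 and P21, 129 higher and 184 lower at P21, with 2969 at an unadjusted p under 0.05. Without P14 replicate 2 the limma count was 0 (1757 unadjusted), and without P14 replicate 1 it was 41 (27 higher and 14 lower). It was 80, 109, 134 and 181 without P21 replicate 2, P21 replicate 3, P7 replicate 2 and P7 replicate 3, and 0 (2070 unadjusted) with the poly-A control as a block, where P21 is 1 array. The 4 probe sets just described did not pass without P14 replicate 2, with adjusted p from 0.0511 to 0.14, while their log2 changes were -4.70 and -5.08 for the falls and 2.11 and 1.64 for the rises. Over all alternatives, the adjusted p ran from 0.00121 to 0.169 for the largest fall (not passing in 5 of 18), from 0.0168 to 0.302 for the next (9 of 18), from 0.00416 to 0.0919 for the largest rise (2 of 17) and from 0.0124 to 0.187 for the next (2 of 17). The falls were also lost without P14 replicate 1 (log2 changes -3.88 and -2.54, adjusted p 0.13 and 0.145) and without P21 replicate 2 (-4.07 and -3.87, 0.0697 and 0.0749). The second of them was also lost without P21 replicate 1 (-3.84, 0.0519), without P21 replicate 3 (-3.72, 0.0742) and with the larger pseudocount (-2.40, 0.0687). With unchanged log2 changes, both falls were lost with no filter (0.0507 and 0.058) and the second with no trend (0.0581). With the poly-A control as a block, where none of the 4 passed, the falls were -2.52 and -3.75 and the rises 2.56 and 1.60.

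The change of the first interval was set against that of the second by a contrast of its own. The probe set with the largest rise from P7 to P14 had a difference of 3.39 (SE 0.31, limma adjusted p = 0.00142), which was 4.80 with a smaller and 1.91 with a larger pseudocount. The most negative difference was -4.12 (SE 0.44, limma adjusted p = 0.0017), for a probe set with signals of 1429 ± 423 at P7, 197 ± 17.4 at P14 and 540 ± 149 at P21. The next, -4.11 (SE 0.41), was that of the probe set with the largest rise from P14 to P21, and was -5.35 with a smaller and -2.34 with a larger pseudocount. The most positive difference, 3.40 (SE 0.89, limma adjusted p = 0.0453), rested on P14 replicate 2, with a signal of 592 against 109 on replicate 1. It was 1.08 (adjusted p = 0.305) without that array and 5.71 (adjusted p = 0.00527) without P14 replicate 1. Over all 18 alternatives its adjusted p ran between these values and passed in 7, and in the other 10 that did not pass the difference was 3.28 to 3.86. In all, 1225 probe sets passed, 601 with the more positive and 624 with the more negative change before P14 (513 and 428 after quantile normalization). Without P14 replicate 1 the count was 95, without P14 replicate 2 it was 53, without P21 replicate 3 it was 806, and with the poly-A control as a block, where P21 is 1 array, it was 68.

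Probe sets called between P7 and P21 had reached a median of 0.784 of their log2 change by P14 (jackknife SD 0.0512). The median was 0.793 from P14 replicate 1 and 0.775 from P14 replicate 2. The share exceeded 0.5 in 78.6% of these probe sets and 1 in 25.9%. A share above 1 only means that the estimated change after P14 ran the other way. Noise can also give this, since the median SE of the change from P14 to P21 was 0.17. Of all probe sets tested, 56 were called as falling and then rising, and 32 as rising and then falling. Among those called between P7 and P21, the median share was 0.799 for those that rose and 0.771 for those that fell. The difference of 0.0279 is close to its jackknife SD of 0.0258.

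**Figure D4:**
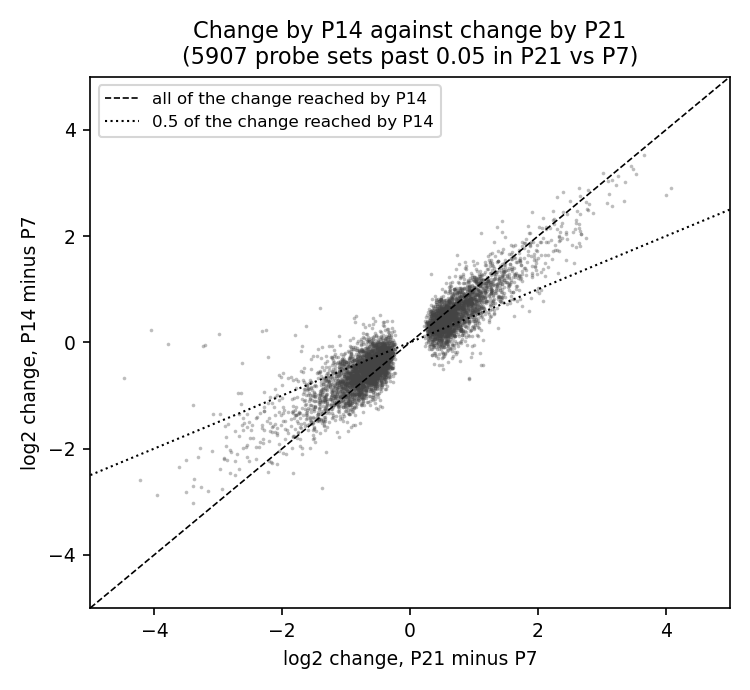
Log2 change from P7 to P14 against log2 change from P7 to P21, 1 point for each of the 5907 probe sets called between P7 and P21, with lines for the whole change and for 0.5 of it. The median share of the change reached by P14 is 0.784.

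The calls of P14 and P21 against P7 shared 1631 rising and 1969 falling probe sets, where independent lists would share 337 and 549. Opposite calls were 3 and 2. The log2 changes correlated across probe sets at r = 0.85, against 0.45 simulated with no effect, and their covariance was 0.289 against 0.0153, a difference of 0.274. Both comparisons use the same 3 P7 arrays, which are too few to split. Part of the excess of shared calls over independent lists may come from them, while the simulated covariance already carries them. Among probe sets called in both intervals, 56 fell and then rose (21.6 for independent lists), 32 rose and then fell (23.7), 29 rose in both (16.6) and 67 fell in both (30.8). The P14 arrays enter the intervals with opposite signs, which adds to the first 2 counts. The log2 changes of the intervals correlated across probe sets at r = -0.05, against -0.60 simulated with no effect, and their covariance was -0.00962 against -0.0227, a difference of 0.0131.

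On the cDNA array, P21 was compared with P7 in 5 hybridisations. As labelled, 0 of 12397 spots passed in limma, with a lowest adjusted p of 0.342 and 1475 spots at an unadjusted p under 0.05. As labelled, the spots closest to passing with one sign in all 5 hybridisations were H3011D03 and H3117F03, with mean log2 ratios of 0.37 (SD 0.10) and 0.38 (SD 0.14), and H3112D12 and H3158B04, with -0.45 (SD 0.21) and -0.51 (SD 0.26). All 4 had an adjusted p of 0.342. The direction of hybridisation 5 is not settled, and with its sign turned their mean log2 ratios were 0.28, 0.28, -0.25 and -0.46 (adjusted p 0.0463, 0.0588, 0.198 and 0.0109). By size, the ratios of Cy5 over Cy3 over all 5 were then led by other spots, H3129A01 with 3.203 (SD 0.47) and H3139A05 with -2.77 (SD 1.02). For H3011D03, H3117F03, H3112D12 and H3158B04 the adjusted p without hybridisation 5 lay between 0.00127 and 0.00896, and over all alternatives between 0.00127 and 1. Hybridisation 5, labelled with exchanged dyes, stood apart. Its log2 ratios, turned to P21 over P7, correlated across spots with those of the other 4 at r = -0.86 to -0.64, while the other 4 correlated with each other at 0.72 to 0.85. The same sign in all 5 hybridisations was found for 7.57% of spots as labelled and for 47.2% as Cy5 over Cy3, where chance gives 6.25%.

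Without hybridisation 5, 5277 spots passed, and with its channels turned, a setting chosen after seeing the data, 5426 passed. In both settings P21 stands in Cy5, or is taken to, in every hybridisation, so age and dye cannot be told apart in these counts and no direction is given for their spots. With an age and a dye coefficient in one fit, 3797 spots passed for dye and 2 for age. These were H3084D04 (adjusted p = 0.000184) and H3096H04 (adjusted p = 0.00906), named after their values were seen. In each the age coefficient rested on hybridisation 5, with log2 ratios of -2.78 and -2.24 against -0.30 to -0.07 and 0.08 to 0.36 in the other 4.

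**Figure D5:**
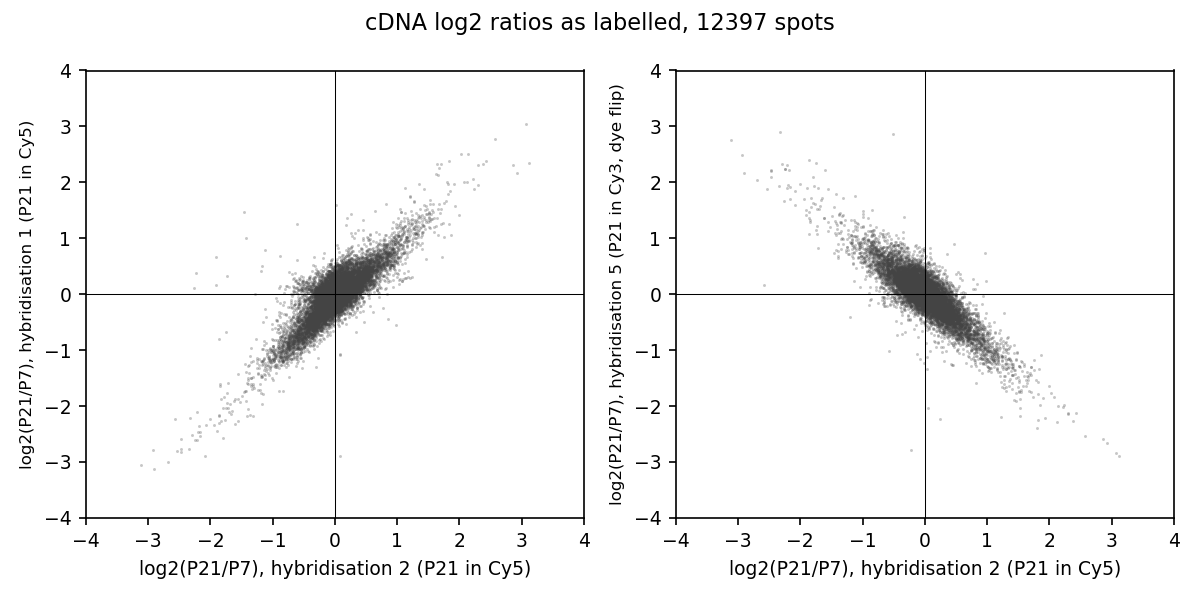
Log2 ratio of P21 over P7 as labelled, 1 point for each of 12397 cDNA spots, with hybridisation 2 on the horizontal axis and hybridisation 1 (left) or hybridisation 5 (right) on the vertical axis. Hybridisation 1 rises with hybridisation 2 (r = 0.85), and hybridisation 5, labelled with exchanged dyes, falls with it (r = -0.86).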

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

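The tests of crossed labels and of dye bias in hybridisation 5, of a round of work shared by arrays of one number, and of other splits of the samples were chosen only after the results they bear on had been seen.

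Hybridisation 5 stood apart from the other cDNA hybridisations, with a mean correlation of -0.733 with the other 4 as labelled. The mean of each of those with its own others, hybridisation 5 included, was 0.366 to 0.421. Among themselves those 4 correlated at 0.72 to 0.85. Clone plate, row and column explained 0.0392 of the variance of the mean log ratio of Cy5 over Cy3. This argues against print position only as far as these give it. They were read from the clone identifiers, and the places of spots on the slide were not tested. Crossed channel labels may account for the way hybridisation 5 stood apart. Its ratio of Cy5 over Cy3 correlated with hybridisations 1 and 2 at a mean of 0.814, close to their mutual 0.847. A dye bias of single spots larger than the age effect may also account for it, since the labels then imply an age variance of 0.00733 (0.00496 and 0.0097 from the 2 partner hybridisations) and a dye variance of 0.169. The implied age SD of 0.0856 lies far below the noise-corrected SD of 0.600 on the oligonucleotide arrays, but spotted arrays can compress ratios, and both explanations stay open, as does the age difference itself.

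The change from P7 to P14 differed from that from P14 to P21 in 1225 probe sets, and called probe sets had a median of 0.784 of their change by P14. The contrast measures how far P14 lay from the midpoint of P7 and P21. The 1225 therefore include probe sets that shifted at P14 alone, and their number does not by itself show early change. One with a difference of -4.11 had a log2 change from P7 to P21 of 0.33 (limma adjusted p = 0.232). An array-wide difference in signal distribution is argued against, since quantile normalization left 941. The counts without each P14 array had a ratio of 0.558. Each leaves a lone P14 array and lies far below 1225, so the ratio cannot decide whether a single P14 array was aberrant. The median share was 0.793 from P14 replicate 1 and 0.775 from P14 replicate 2, which argues against a single aberrant array behind the share. Carry-over of ribosomal RNA is argued against for most of the 1225 probe sets. The 18S control signal at the 5' part was 38.6 and 43.6 at P14 against 155 to 6137 elsewhere. The slope on it within ages was a median of -0.106 of that needed (-0.129 to -0.0190 with 1 array left out). For the 88 probe sets that turned back after P14 it was -0.0284. The slope rests mainly on the P7 and P21 arrays, and a median does not exclude an effect on part of the probe sets. That most developmental change came before P14 stays a hypothesis, and a difference in handling of all P14 arrays together was not tested and stays open.

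The P7 and P21 arrays numbered 1 deviated together from their group means, with r = 0.281 across probe sets. A difference in signal distribution is argued against, since r was 0.283 after quantile normalization. The lowest correlation among the pairs numbered 1 was -0.0442, where a round of work shared by all arrays of one number would raise all of them. The deviations of the 2 P14 arrays are tied to each other (r = -1), so this does not settle it. Arrays of different number reached r = 0.215 and -0.271, so the value is not far outside the others, and no biological explanation was tested.

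Poly-A controls are bacterial transcripts that can be added to RNA before labelling, and each oligonucleotide array carried exactly 1 of 5 at a high mean signal, while the highest of the others was 24.6. The control dap was found on P7 replicate 1 (7115), P7 replicate 2 (8165) and P14 replicate 1 (9580). The control lys was found on P7 replicate 3 (4572), P14 replicate 2 (6117) and P21 replicate 1 (1122). The control phe was found on P21 replicate 2 (6324) and trpn on P21 replicate 3 (7342). On P21 replicate 1 the ratio of the 3' to the 5' signal of lys was 14.4, against 1.72 and 1.67 on the other arrays with lys, while the ratio for actin on that array was 1.13. The labels used here do not mention these controls.

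The log2 ratios of hybridisation 3 had the largest SD of the 5 hybridisations, 0.607 against 0.435 to 0.482. Chance marks about 1 in 20 groups as holding such a distant sample. Between amplified and unamplified RNA, 48 spots differed in log2 ratio over the 4 hybridisations with P21 in Cy5, and 170 differed as Cy5 over Cy3 over all 5. Amplified pools came from 5 pups and unamplified pools from 20.

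The count of 5907 for P21 against P7 compares with a highest count of 0 among other splits of the 6 arrays. The real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05. Each other split mixes the ages, which puts any age difference into its spread, so its count of 0 is no measure of chance. On the cDNA array all 16 sign patterns of the 5 hybridisations gave at least the 0 spots of the labelled one. No pattern can give fewer than 0, so this decides nothing. The highest was 5426, for the pattern that turns hybridisation 5, and 16 patterns are too few for a share under 0.05.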

How the results depend on the processing

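Settings with the poly-A control as a block, with both arrays numbered 1 left out or with turned channels, and all settings for the share reached by P14, were chosen after seeing the data. Between P7 and P21 the count stayed within 1.5 times of 5907 except with the poly-A block (1938), and leaving out 1 array gave 4812 to 5667. For P14 against P7, leaving out 1 array gave 2378 to 4771, with only the 2 lowest, each without a P14 array, outside that range. For P21 against P14 the count was 109 with no filter, 121 with no trend, 572 without both arrays numbered 1, 0 with the poly-A block (2070 unadjusted) and 0 to 463 with 1 array left out (0 without P14 replicate 2, 1757 unadjusted, 41 without P14 replicate 1, 80 and 109 without P21 replicates 2 and 3, 134 and 181 without P7 replicates 2 and 3). For the difference between intervals it was 793 with no trend, 68 with the poly-A block and 53 to 1170 with 1 array left out (53 and 95 without P14 replicates 2 and 1, 806 without P21 replicate 3). Quantile normalization moved the median difference of all probe sets from -0.10 to -6.2e-05 and gave 941 calls. The share reached by P14 was 0.732 without both arrays numbered 1 and 0.712 with the poly-A block, and lay between 0.75 and 0.80 with 1 array left out. Fits without a P14 array assume that the lone array varies like the other ages, and the poly-A block leaves P21 replicate 1 as the only P21 array and 2 residual degrees of freedom, so its lower counts do not show weaker effects. Otherwise the cause was not tested. The replicate number as a block gave 5966, 4406, 323 and 1177, with no call count moved by over 1.5 times. Same-numbered arrays correlated in their deviations at -0.0442 to 0.281. Deviations from a mean of few arrays are tied to each other within an age, so this range does not decide whether the numbers pair the arrays. On the cDNA array, counts other than 0 came from a dye coefficient (2), amplified RNA alone (3008), leaving out hybridisation 5 (0 to 5277 over all hybridisations left out), its channels turned (5426) and its channels turned with unamplified RNA alone (5149). Apart from the dye coefficient, P21 stands in Cy5, or is taken to, in every hybridisation of these settings. Age and dye cannot be told apart in those counts, that of amplified RNA included. Unamplified RNA alone as labelled gave 0 (0 unadjusted), and unpaired channels, without the block, gave 0 (151 unadjusted). No probe set or spot followed through these settings changed sign. The spots H3129A01, H3139A05, H3084D04 and H3096H04 were not followed. The ratio of H3096H04 as labelled was negative in hybridisation 5 and positive in the others, so its sign depends on that hybridisation. The majority of calls turned in 8 of 18 settings for the difference between intervals (among them quantile normalization with 513 positive and 428 negative against 601 and 624, and a filter of 0.5 of the trimmed mean with 646 and 534), and in 1 of 16 for P21 against P14 (27 higher and 14 lower without P14 replicate 1, against 129 and 184). The gene list tests and the comparison between array types, with their alternatives, were not run because the tables used here do not pair these probes with genes. Dim probe sets were called less often, 24.7% in the dimmest and 52.5% in the brightest of 3 groups. The median SE was 0.19 and 0.11 in these groups, and whether it accounts for the fewer calls was not tested.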

Other observations

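The tests and values below were chosen after the data had been seen. Some control probe sets carry a mouse transcript in their identifier, and they were kept in a separate fit. The 3' probe set of PyruCarb rose from 236 ± 8.18 (SD, n = 3) at P7 through 315 ± 8.42 (SD, n = 2) at P14 to 352 ± 11.04 (SD, n = 3) at P21. Its log2 change from P7 to P21 was 0.55 (SE 0.10, limma adjusted p = 0.0012), and it passed in 14 of 15 alternatives, with adjusted p from 0.00075 to 0.0921, the highest with the poly-A block, where P21 is 1 array and the change was 0.55. It also passed between P7 and P14 (log2 change 0.40, limma adjusted p = 0.0186), but not in 4 of 15 alternatives (0.0102 to 0.118): without P7 replicate 3 (0.39), without either P14 array (0.43 and 0.37) and with the poly-A block (0.40). The MA probe set of PyruCarb had a log2 change from P7 to P21 of 0.68 (limma adjusted p = 0.0412), and did not pass in 6 of 15 alternatives (0.0282 to 0.638). The change was 0.42 without P7 replicate 1 (adjusted p = 0.113) and 0.34 with the poly-A block (0.638), while it was 0.68 without either P14 array (0.0528 and 0.0522), 0.59 without P21 replicate 2 (0.127) and 0.63 without P21 replicate 3 (0.111). The 5' and MB probe sets of PyruCarb did not pass, with log2 changes of 0.41 and 0.36. The 3' probe set of TransRec stood at 106 ± 41.5 at P7, 272 ± 108 at P14 and 191 ± 42.1 at P21, and its other probe sets were too dim to be tested. It passed between P7 and P14 (log2 change 1.26, limma adjusted p = 0.011), but not without P14 replicate 1 (0.86, adjusted p = 0.125, where all alternatives gave 0.00223 to 0.125). It also passed between P7 and P21 (log2 change 0.81, limma adjusted p = 0.0363), but not in 5 of 15 alternatives (0.00909 to 0.544), with changes of 0.62 and 0.74 without P7 replicates 1 and 2, 0.86 and 0.65 without P21 replicates 2 and 3, and 0.50 with the poly-A block. For the middle probe set of Gapdh the log2 change from P7 to P21 was 0.36 (limma adjusted p = 0.0416), while the 3' and 5' probe sets did not pass, with 0.28 (adjusted p = 0.124) and 0.34 (adjusted p = 0.0883). The middle one did not pass in 10 of 15 alternatives (0.00328 to 0.82). Its change was 0.17 (adjusted p = 0.0501) after quantile normalization, 0.06 (0.82) with the poly-A block, 0.36 (0.0765) with no trend, and 0.26 to 0.40 without each array other than P21 replicate 1. The 3 b-Actin probe sets did not pass between P7 and P21, with log2 changes of -0.14 to -0.09.

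The deviations of the probe set with the largest fall from P7 to P21 from its age means were followed by other probe sets. Of 5 probe sets looked at, it had the most followers with r above 0.95 and an SD above 0.5, 15, where the others had 9, 2, 0 and 0, and it was kept for that reason. Of 90 other probe sets of like spread, 1 had as many followers. The best of 5 drawn from these 90 would have as many in a share of 0.0556 of draws, so chance correlation over 8 arrays stays open. The geometric mean signal of the followers was 438 on P7 replicate 3 and 371 on P14 replicate 1, against 82.1 to 123 on the other arrays of those ages and 54.9 to 59.8 at P21. The differences within P7 and P14 follow from the choice of followers, since that probe set was itself high on these arrays. Of the followers 6 fell from P7 to P21, 0 rose and 9 did not pass, where 38.6% of all probe sets tested passed. The slope on that probe set within ages and the change from P7 to P21 had a Spearman rho of -0.736 across followers. The same P7 and P21 arrays enter both quantities, so this value decides nothing about a source of RNA present in differing amounts.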
